A study of Mus musculus with 4 samples.

How the data were processed

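The series describes 4 mouse libraries from splenic regulatory T cells (Tregs): an anti-H3K9me3 immunoprecipitate and an input from wild-type cells, and the same pair from KAP1-deficient cells. The authors deposited 1 table for the series, with whole-number read counts around transcription start sites for 51121 Ensembl mouse gene identifiers, per the file headers. It has 2 columns, which the headers name by genotype: Foxp3-cre with wild-type Kap1, and Foxp3-cre with the floxed Kap1 allele. The headers do not say whether a column is immunoprecipitate or input. Each column was taken as the H3K9me3 library of its genotype because the design text describes sequencing of the precipitated chromatin of both genotypes; this assignment was made from the descriptions and was not tested on the values. No column was analysed as an input library.

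The submitters' processing notes name Bowtie2 2.2.9, a short-read aligner, Picard 2.1.1, a toolkit whose uses include marking duplicate reads, bedtools 2.26.0, an interval toolkit, and the mouse build mm10. The role of each tool, the width of the window around a start site, the gene annotation, and any filter on mapping quality or duplicates are not given in the sources used here. Those settings could change the counts: strict mapping filters empty windows in repeated sequence, and duplicate removal lowers high counts. Per the labels' protocols, libraries were made with a template-switching ChIP-seq kit from sonicated chromatin and size-selected before sequencing. Where start sites lie close together their windows could share reads, so windows are not independent of each other.

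The analysis was planned as H3K9me3 over input with named genes and gene lists, and departed from that plan in 2 ways. With no column named as input, enrichment over input, the input comparison and the median difference over enriched windows were not computed. The genotypes were compared on the 2 columns alone. Of the 51121 identifiers, 0 matched a symbol in the gene table used here (no Ensembl identifiers), so the 21 gene lists fixed before the data were examined, and the 8 genes to be named whatever their values (among them the KAP1 gene and Foxp3), are not reported. Positions and GC content of windows were not analysed for the same reason. No column of values was left unused (0).

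With 1 library per genotype no spread between replicates can be estimated, so no edgeR or other test between genotypes was made and no p-value is given. Poisson and binomial intervals and limits cover counting error only, bootstrap intervals cover the variation between windows, and both kinds compare these libraries, not the genotypes. Counts were scaled to each library's total over all windows, which removes any difference in total H3K9me3 between the genotypes. Windows with a mean of at least 5 reads over the libraries entered the comparison (35540 windows). The log2 ratio of KAP1-deficient over KAP1-sufficient reads was taken after adding 2 reads, scaled to library size. A window was called where this ratio was at least 2-fold in either direction and the exact (Clopper-Pearson) 95% interval of its share of reads excluded the share of the whole library. The calls were set beside 1000 simulated splits in which each window's reads were divided at random at the library ratio. The fixed rule for named windows ranked calls by the near limit of the interval. It was restricted to the first 2 windows in each direction, because identifiers without gene names say little, and the window with the most reads was added after its values were seen.

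Variation of read density between windows beyond counting noise was computed by moments: the Poisson variance was subtracted from each library's variance, and the covariance between libraries was divided by the resulting standard deviations. The 2 windows with the most reads were left out, and 95% intervals came from 1000 bootstrap resamples of windows. The calling was tested on simulated data drawn from the real depths with 200 windows changed. It recovered 66.0% of 4-fold changes among 33605 windows and 20% of 2-fold changes among 33783 windows, all in the right direction, and made 906 and 968 calls among unchanged windows. A 2-fold change lies at the threshold of a call, so its recovery is limited by the rule at any depth. Alternatives covered scaling, the reads added, the filter and, chosen after seeing the data, the interval and the expected ratio. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.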

Results

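To ask how the repressive histone mark H3K9me3 at gene starts differed when Tregs lacked KAP1, chromatin of sorted splenic Tregs was profiled by ChIP-seq. KAP1, also known as TRIM28, is a co-repressor that zinc finger proteins bring to DNA and that recruits H3K9 methyltransferase activity. Tregs are the T cells that restrain immune responses and are defined by the transcription factor Foxp3; the table's headings name Foxp3-cre, a recombinase driven from that locus, with an intact or a floxed Kap1 allele. Read counts were compared over 51121 windows around transcription start sites, with 1 library per genotype. The headings give the genotype and not the antibody, so the columns are called here the KAP1-sufficient and the KAP1-deficient library, and their reading as H3K9me3 rests on the study's description. Identifiers were not paired with gene names, so results are given for start site windows as a whole and for a few windows by identifier.

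Coverage was shallow in both libraries. The KAP1-sufficient library held 480326 reads in windows, with a median of 10 reads per window and quartiles of 5 and 13. The KAP1-deficient library held 228009 reads, with a median of 4 and quartiles of 2 and 6, so the former was 2.11 times deeper. No reads from either library fell in 6147 windows, 12.02% of the total. Where reads could be mapped and kept, a count of 0 allows a level of up to 3 reads in each library, a one-sided limit at 95% confidence. Whether reads could be counted in these windows was not tested, so they are not shown to be low in H3K9me3. A further 414 windows were at 0 in the KAP1-sufficient library alone, and counting noise at a common ratio gives 416. In the KAP1-deficient library alone 2171 were at 0, against 1925 from counting noise. Both expectations give every window the same share of KAP1-deficient reads. Windows with few reads had a lower share, as given below, which would raise the 1925. The gap therefore cannot be read apart from that trend.

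**Figure D1:**
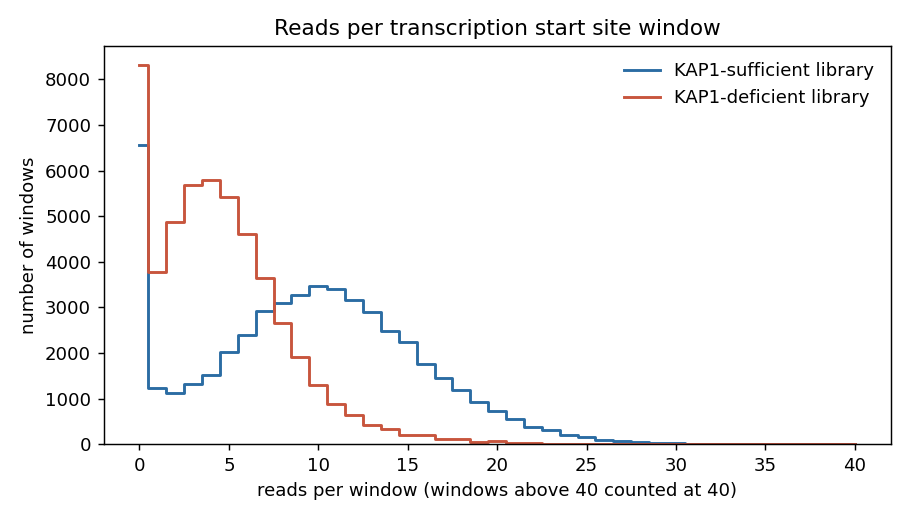
Number of windows (vertical axis) by reads per window (horizontal axis) in the KAP1-sufficient and KAP1-deficient libraries, with windows above 40 reads counted at 40. Apart from the windows at 0, each library has a single broad peak, around its median of 10 and 4 reads, with no separate group of windows of high counts.

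Few start site windows stood far above the others in either library. The window of ENSMUSG00000095280, singled out after its values were seen, held the most reads, 615 in the KAP1-sufficient library (95% Poisson interval 567 to 666) and 408 in the KAP1-deficient library (369 to 450). The next highest window held 100 and 40 reads, and the other windows at most 46 and 36. After scaling to total reads, the KAP1-deficient to KAP1-sufficient ratio of ENSMUSG00000095280 was 1.40 (95% interval 1.23 to 1.59), below the 2-fold size set for a call. With counting noise subtracted, read density varied between windows with a coefficient of variation of 39.7% in the KAP1-sufficient library (95% bootstrap interval 39.3 to 40.2) and 52.3% in the KAP1-deficient library (51.5 to 53.0), over 44972 windows with at least 1 read.

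Windows with many reads in one library tended to have many in the other. Across these windows, which are not independent replicates, the read counts had a Pearson r of 0.53 and a Spearman rho of 0.52. With counting noise subtracted, the densities of the libraries correlated at 0.88 (95% bootstrap interval 0.87 to 0.89). The same computation gave 0.79 (0.77 to 0.82) over windows past the low-count filter. That filter selects on the same reads, so the Poisson subtraction is not exact there and the values are not like for like. Neither library was set against an input. The part of the correlation, and of the variation between windows above, that reflects H3K9me3 was therefore not determined.

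Between the genotypes, most start site windows differed by no more than their reads could resolve. Of 35540 windows past the filter, 644 (1.81%) were called at least 2-fold lower in the KAP1-deficient library and 885 (2.49%) at least 2-fold higher. Random division of the same reads at the library ratio gave 472 lower windows on average (399 to 546 over 1000 simulations) and 532 higher windows (457 to 611). The observed counts were thus 1.36 and 1.66 times those from counting noise, an excess of 172 lower and 353 higher windows. Counting noise gave 1004 calls in all on average, against the 1529 observed. Higher windows made up 57.9% of the calls, against a mean of 53.0% in the simulations, whose highest values in separate runs of 1000 (57.8% and 58.7%) lay on either side of it. This split depended on the setting, and so did its simulated mean. With scaling by the median of ratios the split was 67.7%, against a simulated mean of 64.0% (59.4% to 68.8%). With 10 reads added it was 49.3%, against 28.8% (16.1% to 42.9%). The observed split was above the simulated mean at each of these settings. The log2 ratio had a median of -0.05 and an SD over windows of 0.69, and the simulated SD was 0.64. The squared deviations of the window shares were 1.17 times the binomial variance (95% bootstrap interval 1.16 to 1.19), outside the 0.98 to 1.02 of the simulations. The bootstrap interval and all simulated ranges treat windows as independent, so they are too narrow where windows share reads. Differences in total H3K9me3 between the genotypes cannot be seen on this scale, and without replicates none of these counts separates genotype from library.

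**Figure D2:**
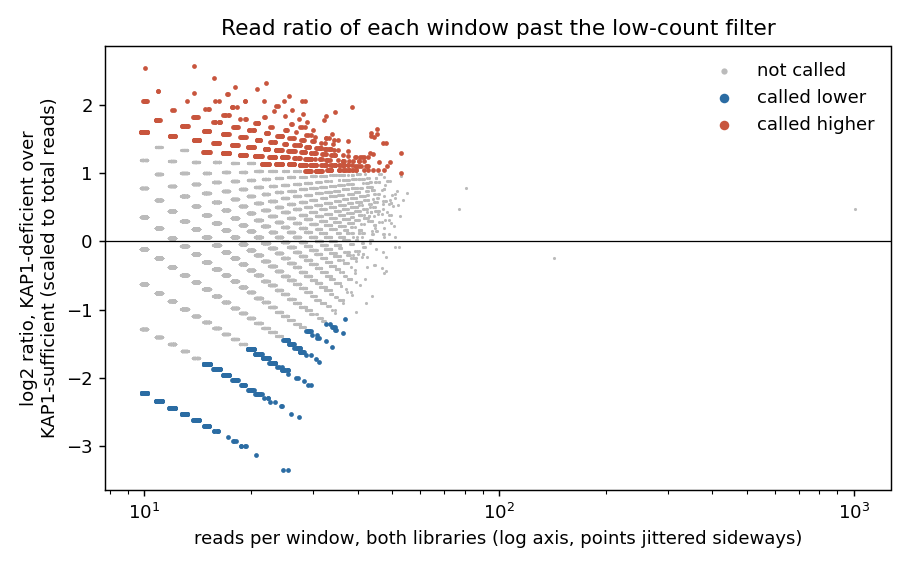
Log2 ratio of KAP1-deficient over KAP1-sufficient reads, scaled to total reads (vertical axis), against reads per window over both libraries (log horizontal axis), 1 point per window past the filter. The 644 windows called lower (blue) and the 885 called higher (red) lie at the edges of a cloud whose width shrinks as reads increase. More KAP1-deficient reads move a point up and to the right, and more KAP1-sufficient reads move it down and to the right.

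The calls ranked first by the near limit of their interval rested on 25 reads or fewer over both libraries. The windows of ENSMUSG00000004071 and ENSMUSG00000044030 each held 25 reads in the KAP1-sufficient library (95% Poisson interval 16.2 to 36.9) and 0 in the KAP1-deficient library. The upper 95% limit of the KAP1-deficient to KAP1-sufficient ratio, which takes in the counting error of both, was 0.33 for each, so each was lower by a factor of 2.99 or more at that level. No other window had these counts, and whether this pair of windows shares reads was not tested. In the other direction, the window of ENSMUSG00000110754 held 2 reads in the KAP1-sufficient and 12 in the KAP1-deficient library, a ratio of 12.6 (95% interval 2.81 to 116). The window of ENSMUSG00000037813 held 1 and 9 reads, a ratio of 18.96 (2.63 to 831). These are the extremes of 35540 windows, so their intervals, set for 1 window at a time, are too narrow for them.

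The KAP1-deficient library was relatively richer in the start site windows with the most reads. It supplied 32.2% of reads over all windows (95% interval 32.1 to 32.3). When windows past the filter were sorted into deciles by their reads over both libraries, its share was 30.5% (30.0 to 31.0) in the lowest decile, with 10 to 11 reads per window. It was 31.2% (30.9 to 31.6) in the fifth decile, 32.9% (32.6 to 33.2) in the ninth and 36.3% (36.1 to 36.6) in the top decile, with 27 reads or more. On the scale of total reads, the KAP1-deficient to KAP1-sufficient ratio was 0.92 (0.90 to 0.94) in the lowest decile and 1.20 (1.19 to 1.22) in the top decile. Sorting on reads of both libraries favours windows that are high in either library. Without the low-count filter, the same sort of all windows with at least 1 read gave 31.6% (30.8 to 32.3) in the lowest decile, a lower 30.0% (29.5 to 30.5) in the second, 31.5% (31.1 to 31.8) in the seventh and 35.8% (35.5 to 36.0) in the top decile, so the share did not rise throughout. Windows were then sorted on a random 50% of the KAP1-sufficient reads, also without the filter, and measured on the remaining reads of both libraries from such a division. The KAP1-deficient share was 31.5% (30.8 to 32.1) in the lowest decile and 33.7% (33.3 to 34.1) in the top decile. This sort used fewer reads per window and favours windows high in the KAP1-sufficient library, so its smaller increase is not a corrected value. In the 3554 windows with the most reads by a sort of this kind, called on the remaining KAP1-sufficient and all KAP1-deficient reads, 117 were higher and 58 lower in the KAP1-deficient library. Counting noise gave 48.4 higher (30 to 70 over 1000 simulations) and 51.2 lower (30 to 74). The pooled KAP1-deficient to KAP1-sufficient ratio of these 3554 windows was 1.08 (1.06 to 1.10). A shift common to these windows and differences of single windows were not told apart in the calls. These intervals are exact binomial ones and treat reads as independent.

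**Figure D3:**
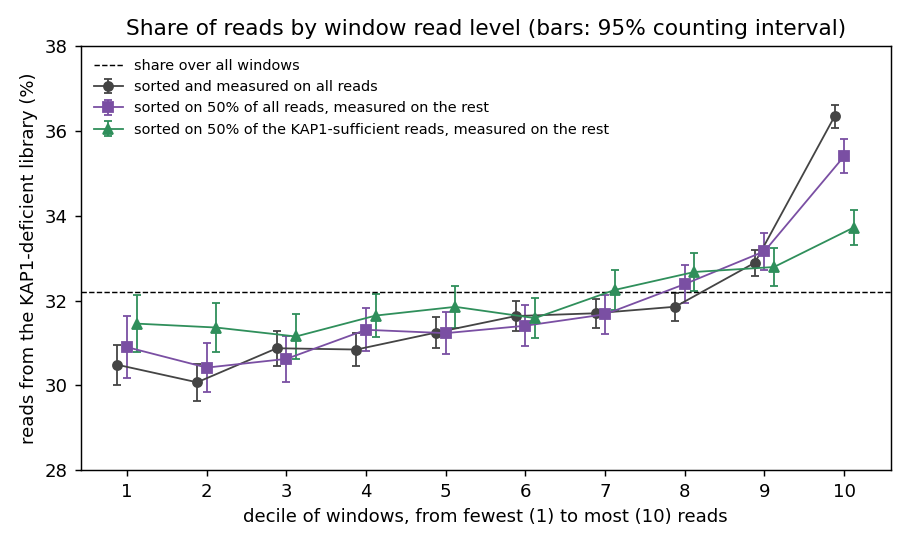
Share of reads from the KAP1-deficient library in percent (vertical axis, which does not start at 0) by decile of windows from fewest to most reads (horizontal axis), with 95% counting intervals and the share over all windows as a dashed line. The share sorted and measured on all reads goes from 30.5% in the lowest to 36.3% in the top decile of windows past the filter; the other lines, without the filter, sort on a random 50% of all reads or of the KAP1-sufficient reads and measure on the rest.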

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

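All values are from 1 library per genotype, and at a median of 10 and 4 reads per window depth limits every single-window statement. In simulated data 66.0% of 4-fold changes were recovered. Of 2-fold changes 20% were recovered, but such a change lies at the 2-fold threshold of a call, so this value does not measure depth alone. The counts of 644 lower and 885 higher windows stayed within 1.5 times of these values with 0.5 reads added, no filter, scaling by the median of ratios (514 and 1076, a log2 shift of -0.06) and, chosen after seeing the data, an expected ratio per decile of reads (597 and 776, against 446 and 516 simulated). Identifiers were unique, so taking each row on its own altered nothing. With 10 reads added, which shrinks ratios at this depth, the counts were 114 lower and 111 higher, against 83.7 and 34.2 simulated. With a mean of at least 20 reads they were 0 and 35 among the 296 windows left, against 4.37 and 1.84 simulated. This choice favours windows high in either library. Another 296 windows were chosen on 50% of the KAP1-sufficient reads and called on the remaining reads, an alternative chosen after seeing the data. They gave 2 lower and 17 higher, against 4.23 and 4.39 simulated, at a pooled KAP1-deficient to KAP1-sufficient ratio of 1.17 (1.12 to 1.23). With a 99% interval, chosen after seeing the data, the counts were 100 and 238, against 66.1 and 86.9 simulated. The 36.3% share in the top decile was 35.8% with no filter. With a mean of at least 20 reads it was 40.3% (38.4 to 42.2). That is the top decile of 296 windows and not of 35540, and it includes ENSMUSG00000095280, so the sets are unlike. The correlation of window densities (0.88) was 0.92 (0.87 to 0.95) with the 2 most-read windows included and 0.79 past the filter, both chosen after seeing the data. The filter selects on the same reads, which itself alters the 0.79. Not run were scaling on background windows, autosomes alone, GC correction and the matching of random gene lists. They lacked columns named as input, coordinates or names. Enrichment over input, the input difference, the gene lists and the median over enriched windows have no value under any setting. No paired analysis was possible because each genotype had 1 library.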

Other observations

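The tests of the most-read windows and of the correlation of densities were chosen after the related results were seen; the other tests below were set before their results were computed.

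The share of reads from the KAP1-deficient library was 30.5% in the lowest decile by reads and 36.3% in the top decile of windows past the filter. Without the filter it was 31.6% (30.8 to 32.3) in the lowest decile, 30.0% (29.5 to 30.5) in the second and 35.8% (35.5 to 36.0) in the top one, so the increase lies above the lowest decile. The 2 windows with the most reads held too few reads to account for it. They held 615 and 408 reads, and 100 and 40, of the top decile's 72672 KAP1-sufficient and 41484 KAP1-deficient reads. Without them the share in the top decile was 36.3% (95% interval 36.0 to 36.5), a result these numbers settled in advance. Windows were also sorted, without the filter, on a random 50% of the reads and measured on the remaining reads. The share in the top decile was then 35.4% (35.0 to 35.8). This value cannot decide whether sorting and measuring on the same reads contributed. Counting noise at a common ratio gives the same share in every decile, so it would give no increase under either sort. A window's excess in either library remains in both parts of a random division. Sorting on 50% of the KAP1-sufficient reads alone, also without the filter, gave an increase from 31.5% (30.8 to 32.1) to 33.7% (33.3 to 34.1), which is what a smaller share of evenly spread background reads in the KAP1-deficient library would give, so that remains a possible explanation. A difference between the genotypes, GC bias of a library and uneven duplicate removal remain open and untested, because genotype and library are the same thing here and window sequences were not analysed.

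Ratios of single windows spread more than counting noise, at 1.17 times the binomial variance. The increase of the share with reads does not explain this as a whole, since the ratio was still 1.15 with the share set per decile of reads (0.98 to 1.03 in simulated splits). A different amount of evenly spread background would leave the densities of the libraries perfectly correlated, and an upper limit under 0.95 was set to count against it. The densities of 44972 windows correlated at 0.88 (0.87 to 0.89), so it is unlikely to be the whole cause in these windows. With the 2 most-read windows included the upper limit was 0.952, which does not pass that bound, so the exclusion does not extend to the full set. Window-specific differences may come from genotype or from library preparation, and these cannot be told apart with 1 library each. A planned check of chromosome copy and sex through X and Y windows was not run, so a difference in these was not tested either.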
